A study of Mus musculus with 8 samples.

How the data were processed

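RNA sequencing was performed on 8 mammary tumours grown from EMT6 cells, a mouse mammary carcinoma line, in syngeneic Balb/c mice. Per the labels, 4 tumours came from animals given IgG and 4 from animals given granzyme B, which the series title names as GrB-Fc-KS49, a human fusion protein that carries granzyme B and is directed to the membrane protein EMP2. Treatment was given 3 times within 10 days. Replicate numbers only name libraries and pair nothing across the groups. The title of 1 library per group (IgG control replicate 1 and GrB-Fc-KS49 replicate 3) ends in U, a suffix whose meaning is not given in the sources used here. The sources used here do not state that each tumour came from a different animal, so p-values measure the spread between these tumours.

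Per the labels' protocols, poly(A) RNA was enriched, fragmented and reverse transcribed with random primers, and dUTP was built into the other cDNA strand, with the KAPA Stranded mRNA-Seq kit. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.19.1.403 and aligned with STAR to the GRCm39 mouse genome. The STAR version, the gene quantifier, the annotation release and the use of strand in counting are not given in the sources used here. The authors deposited a table of estimated counts per gene, of which 46.0% to 47.7% of values per library were whole numbers to the precision of the table (no fractional part beyond rounding error), zeros included, and 43.9% to 46.1% of the values above 0, and a table of CPM (counts scaled to 1e6 per library) made by dividing the same counts by the library total after adding 0.0001 count. Both tables held 26709 genes, each with a total of at least 10 counts over the 8 libraries. Because the use of strand in counting is not given, reads of a gene and of a gene on the opposite strand at the same place cannot be told apart here, and the division of reads among near-identical copies is likewise unknown. Coordinates are those of the deposited table on GRCm39, written 1-based.

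Estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with the treatment group, which left 19718 genes. Library totals were scaled by the trimmed mean of M-values (TMM), and printed CPM are TMM-scaled. The groups were compared with edgeR 4.0.16 by robust quasi-likelihood F tests in R 4.3.3, with p-values adjusted by Benjamini-Hochberg over all genes tested and called at an adjusted p under 0.05. Total counts ran from 74.0 to 82.6 M per library. The biological coefficient of variation was 27.8%. On counts simulated from the real means and library sizes, with 200 of 19485 genes changed and, besides these, 2 lists of 20 genes moved 1.5-fold and 2 moved 2-fold, this test recovered 25.4% of the 1.5-fold, 61.2% of the 2-fold and 92.4% of the 4-fold changes among the 200. Of its 174 calls over all simulated genes, list members included, 8.6% were of genes that had not been changed. The simulation drew each gene independently and gave both groups the same dispersion. The real treated tumours differed more from each other than the controls did, so these shares need not hold for the real data.

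Before the data were examined, the test, its samples, the gene lists, the rule for naming genes and most alternatives were fixed. There were 46 lists of cell type markers, pathways and tissues that a dissected tumour could carry along, with 808 entries, of which 16 were not measured. The 43 lists with at least 5 tested members were tested with fry (limma 3.58.1), whose directional p-value asks whether the genes of a list move, on balance, in 1 direction, and whose mixed p-value asks whether they change in either direction. A score per library, the mean z-scored log2 CPM of a list's tested members, was compared by an exact 2-sided permutation test over 70 splits, for which the smallest possible p is 0.0286. The p-values of a list's members were also adjusted over the list alone. The rule for naming genes took Emp2 and Gzmb, up to 12 genes per direction past the threshold, of which there were 0, then the 5 genes per direction with the smallest unadjusted p at a mean CPM of at least 1, up to 4 members with the smallest p from each list, and any gene behind a count of 5 or fewer. Immunoglobulin and T cell receptor segments and predicted genes were left out of the part taken by smallest p. Genes named outside this rule are said to have been chosen after their values were seen.

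The alternatives tried were other scaling factors, no low-count filter and a stricter one, DESeq2 1.42.0, limma-voom with and without sample weights, limma on log2(CPM + 1) and log2(CPM + 0.25) from the deposited CPM, each library left out in turn, both libraries with the U suffix left out, the suffix as a covariate, other thresholds, camera in place of fry, and lists without shared members. After the data were seen, a correction was added that removes each library's smooth trend (mgcv 1.9.3) with transcript length and GC content, taken from the GENCODE M21 transcripts matched by gene identifier, for 19341 of the tested genes (98.1%). That release belongs to another genome build, so no coordinate was taken from it.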

Results

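The expression of 26709 genes was measured in 8 EMT6 mammary tumours from Balb/c mice, 4 treated with IgG and 4 with GrB-Fc-KS49, a granzyme B fusion protein directed to EMP2. Total estimated counts were 78.5 ± 3.5 M in IgG controls and 79.3 ± 3.1 M in GrB-Fc-KS49 tumours (SD, n = 4 each). The comparison asks how the agent alters the tumour and the immune cells within it.

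Transcripts of lymphocytes and of antigen presentation had higher group means in GrB-Fc-KS49 tumours, with a wide spread between those tumours, and so had markers of skeletal muscle, skin and adipocytes, whose lists had median log2 fold changes of 2.88, 5.23 and 1.69 against 1.97 for T cells. Each of these medians was carried in large part by 1 tumour, with muscle at 1.20 and T cells at 1.29 without GrB-Fc-KS49 replicate 1, skin at 0.78 without replicate 2 and adipocytes at 0.50 without replicate 3. Cd3d, a subunit of the T cell receptor complex, was at 2.11 ± 2.05 CPM against 0.201 ± 0.105 CPM in IgG controls (SD, n = 4 each), and H2-Ab1, an MHC class II chain, was at 302 ± 319 CPM against 40.5 ± 20.6 CPM. Without GrB-Fc-KS49 replicate 1 the treated means of Cd3d and H2-Ab1 were 1.16 and 163 CPM. Rplp1, a ribosomal protein gene, was at 692 ± 152 CPM against 449 ± 18.8 CPM. Mki67, a marker of cycling cells, was at 255 ± 39.3 CPM against 348 ± 12.8 CPM and Fn1, which encodes fibronectin, was at 2438 ± 709 CPM against 3811 ± 112 CPM. None of these genes passed the test over all genes.

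By edgeR's quasi-likelihood test, 0 of 19718 genes passed a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.0619. At an unadjusted p under 0.05 there were 6915 genes, 3404 higher and 3511 lower in GrB-Fc-KS49 tumours, 35.1% of those tested against 5% by chance. The 4 treated and the 4 control tumours did not overlap in 2039 genes higher and 3023 genes lower, which is 25.7% of those tested against 2.9% by chance. DESeq2 called 4726 genes, limma-voom called 1 and limma-voom with sample weights called 1291. The gene called by limma-voom was Gm15655, a long noncoding RNA lower in GrB-Fc-KS49 tumours, named after its values were seen. Without GrB-Fc-KS49 replicate 1 edgeR called 1260 genes and without replicate 4 it called 3447. With both libraries of the U suffix left out edgeR called 0 genes with 5345 at an unadjusted p under 0.05, and with the suffix as a covariate it called 0 with 6990, while 1 library with the suffix per group allows no test within it. Upper quartile scaling moved the share of higher genes among those at an unadjusted p under 0.05 from 49.2% to 61.4%, and removal of the length and GC trends moved it from 48.7% to 32.6% on the genes it covers. That removal also took the median log2 fold change of all genes it covers from 0.03 to -0.07, a shift that lowers this share.

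The treated tumours differed more from each other than the control tumours did. Pearson's r of log2 CPM across genes was 0.984 to 0.992 between control libraries and 0.960 to 0.982 between treated libraries. The first principal component, with 47.9% of the variance, placed the controls between -46.7 and -21.4 and GrB-Fc-KS49 replicates 1 to 4 at 99.9, 48.7, 3.0 and -8.0. Across 12503 protein-coding genes the deviation of a library from the gene means rose with transcript length in every control (Spearman's rho 0.20 to 0.25) and fell with it in every treated library (-0.26 to -0.10). With GC content rho was -0.30 to -0.19 in controls and 0.08 to 0.23 in treated libraries. Genes are not independent replicates in these values.

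**Figure D1:**
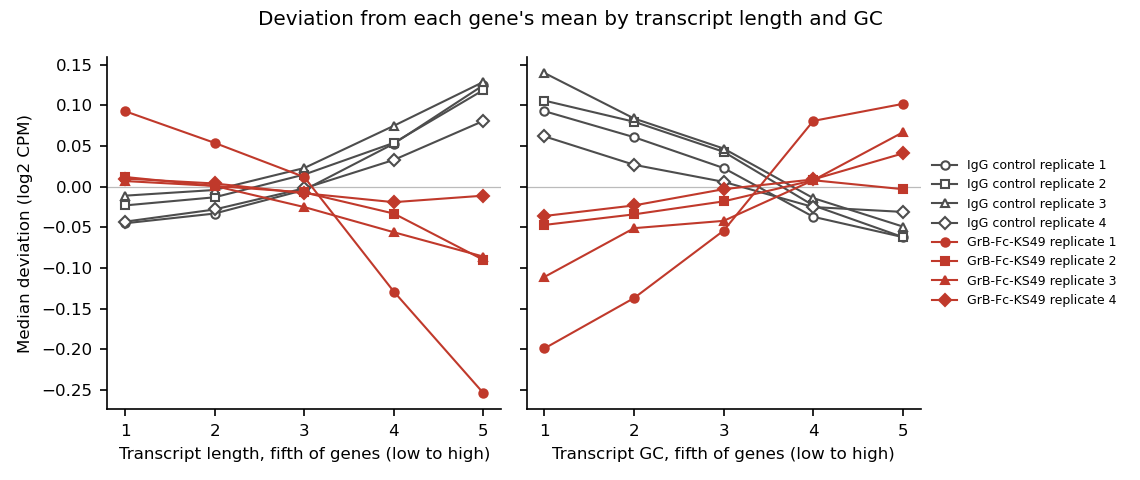
Median deviation of log2 CPM from each gene's mean over the 8 libraries (y axis) for protein-coding genes in 5 bins of equal size ordered by transcript length (left) and GC content (right), with 1 line per library. Controls run up and treated libraries run down with length, from 0.093 to -0.254 in GrB-Fc-KS49 replicate 1.

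Emp2, the mouse transcript of the protein that the agent binds (ENSMUSG00000022505, chromosome 16, 10099613 to 10131832, minus strand, GRCm39), was at 135 ± 29.7 CPM in GrB-Fc-KS49 tumours and 134.5 ± 13.4 CPM in controls (SD, n = 4 each). Its log2 fold change was 0.01 with a standard error of 0.15 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.977). Mouse Gzmb (ENSMUSG00000015437, chromosome 14, 56496295 to 56499717, minus strand), a granule protease of cytotoxic lymphocytes, was at 9.86 ± 11.9 CPM against 2.27 ± 0.949 CPM, with a log2 fold change of 2.12 and a standard error of 0.99 (edgeR quasi-likelihood, adjusted p = 0.164). Gzmb was at 26.66, 9.83, 0.51 and 2.44 CPM in GrB-Fc-KS49 replicates 1 to 4, and without replicate 1 its log2 fold change was 0.91. The agent is a protein, so the human granzyme B it carries adds no transcript to these counts.

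The 5 higher and 5 lower genes with the smallest unadjusted p had no overlap between the groups, and each had an adjusted p of 0.0619 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment, short of the threshold. Saa3, an acute phase serum amyloid A protein (ENSMUSG00000040026, chromosome 7, 46361422 to 46365124), was at 26.8 ± 4.23 CPM against 12.5 ± 1.98 CPM (log2 fold change 1.10, SE 0.15). Pcdhgc4, a gamma protocadherin (ENSMUSG00000023036, chromosome 18, 37948132 to 37974926), was at 101 ± 20 CPM against 42.8 ± 9.70 CPM, and since it shares exons with the other gamma protocadherins its count depends on how shared reads were divided. Nphs1, which encodes nephrin (ENSMUSG00000006649, chromosome 7, 30157740 to 30186648), was at 166 ± 21.9 CPM against 105 ± 4.14 CPM. Rabac1, a Rab acceptor of the Golgi, and Map1lc3a, an autophagosome protein, had log2 fold changes of 0.53 ± 0.08 and 0.54 ± 0.09 (SE). Osmr, the oncostatin M receptor (ENSMUSG00000022146, chromosome 15, 6843058 to 6904450), was at 55.6 ± 4.88 CPM against 84.7 ± 6.71 CPM (log2 fold change -0.61, SE 0.09). Cubn, which encodes the endocytic receptor cubilin (ENSMUSG00000026726, chromosome 2, 13281149 to 13496624), was at 2.59 ± 0.330 CPM against 4.71 ± 0.331 CPM. Plekhh2 and the zinc finger genes Zfp644 and Zfp729a had log2 fold changes of -0.62, -0.57 and -0.51.

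**Figure D2:**
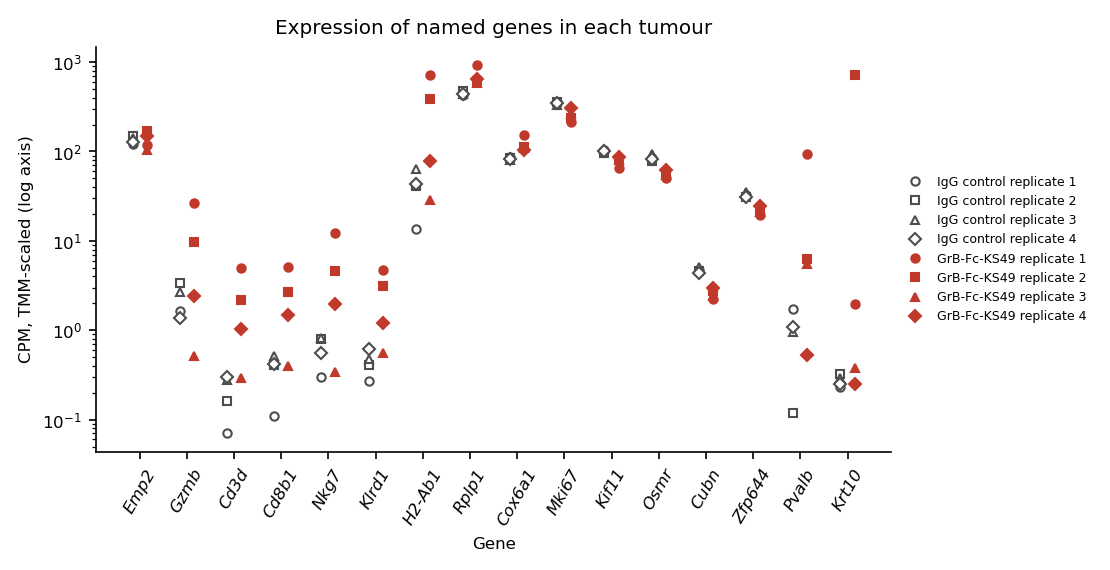
TMM-scaled CPM (log y axis) of 16 named genes in each of the 8 tumours, open grey for IgG control and filled red for GrB-Fc-KS49, 1 symbol shape per replicate number. The lymphocyte genes Cd3d, Cd8b1, Nkg7 and Klrd1 reach their highest values in GrB-Fc-KS49 replicates 1 and 2, while Osmr, Cubn and Zfp644 are lower in all 4 treated tumours.

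Of the 43 gene lists tested, the directional test of fry called 0 at a Benjamini-Hochberg adjusted p under 0.05, the smallest being 0.211, and its mixed test called 1, the apoptosis and p53 target list. The mixed call was lost without IgG control replicates 1, 2, 3 or 4 (adjusted p 0.172, 0.182, 0.182 and 0.0718), without GrB-Fc-KS49 replicate 2 (0.111), without both U libraries (0.106), with no low-count filter (0.0632) and after removal of the length and GC trends (0.0682). Camera, which tests 1 direction, gave that list an adjusted p of 0.153 with the preset and 0.742 with the estimated correlation. The number of lists called by the mixed test also rose in other settings. It was 8, 23 and 11 without GrB-Fc-KS49 replicates 1, 3 and 4, 3 on log2(CPM + 1) and 2 with the suffix as covariate. By the directional test 6 lists were at an unadjusted p under 0.05, a count of 3 without IgG control replicate 3 or GrB-Fc-KS49 replicate 2, 20 without GrB-Fc-KS49 replicate 3 and 10 without replicate 4. Camera with its preset correlation of 0.01 called 28 lists, 25 higher and 3 lower (proliferation, EMP2 and its reported partners, and epithelial-mesenchymal transition). None of the 28 held with an estimated correlation, where the smallest adjusted p was 0.653. The score of 5 lists separated all treated from all control tumours, with an exact permutation p of 0.0286 each, the smallest this design can give, and 0.246 after adjustment over the lists. These were ribosomal protein, oxidative phosphorylation, B cell and dendritic cell, all higher, and epithelial-mesenchymal transition, lower. The dendritic cell list separated the groups only narrowly, with -0.22 in GrB-Fc-KS49 replicate 4 against -0.23 in IgG control replicate 4. So did epithelial-mesenchymal transition, with 0.06 in GrB-Fc-KS49 replicate 4 against 0.08 in IgG control replicate 3. No member of any list passed over all genes, so the counts of members below are those adjusted over the list alone. With 35.1% of all tested genes at an unadjusted p under 0.05, many members of a list can pass in this way without a change particular to that list.

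**Figure D3:**
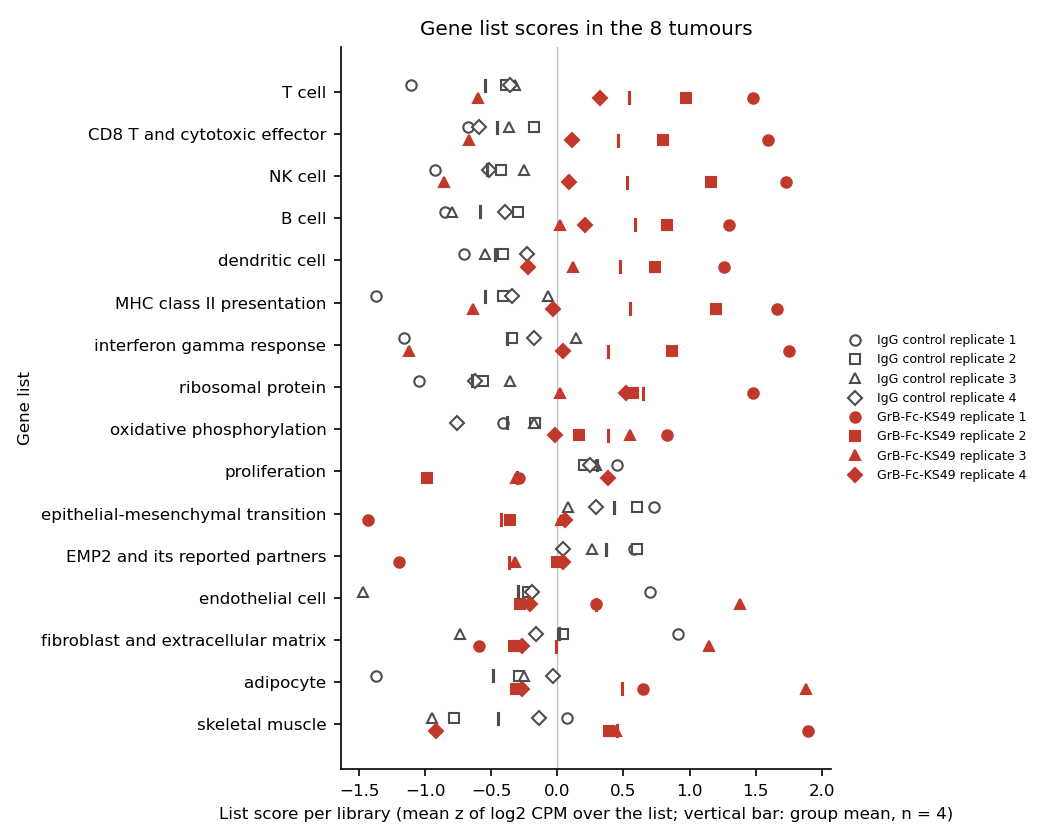
Score of 16 gene lists in each tumour (x axis, mean z-scored log2 CPM over the list, no unit), open grey for IgG control and filled red for GrB-Fc-KS49, with a vertical bar at each group mean (n = 4). GrB-Fc-KS49 replicates 1 and 2 lie above the controls in the lymphocyte lists, with T cell scores of 1.48 and 0.97, while replicate 3 is at -0.60.

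Among lymphocyte lists, 17 of 18 tested T cell genes were higher in the treated group mean, 14 of them passing when adjusted over the list alone (fry adjusted p = 0.297). Lat, a T cell signalling adaptor, was at 1.98 ± 1.78 CPM against 0.465 ± 0.125 CPM (SD, n = 4 each). In the list of CD8 T and cytotoxic effector genes 16 of 17 were higher and 11 passed when adjusted over the list alone (fry adjusted p = 0.297). Cd8b1, a chain of the CD8 coreceptor, was at 2.41 ± 1.99 CPM against 0.362 ± 0.175 CPM, Nkg7, a cytotoxic granule protein, at 4.77 ± 5.22 CPM against 0.617 ± 0.244 CPM, and Tbx21, the transcription factor T-bet, had a log2 fold change of 2.92 ± 0.86 (SE). Without GrB-Fc-KS49 replicate 1 the treated means of Lat, Cd8b1, Nkg7 and Pdcd1 were 1.11, 1.53, 2.31 and 2.26 CPM, and the log2 fold change of Tbx21 was 1.88. In the NK cell list all 12 were higher and 3 passed, among them the receptor genes Klrd1 and Klrb1c, with log2 fold changes of 2.44 and 1.88 (1.88 and 1.19 without GrB-Fc-KS49 replicate 1). In the list of CD4 and regulatory T cell genes 10 of 12 were higher and 4 passed, Cd4 and the costimulatory receptor Tnfrsf4 among them. In the B cell list all 10 were higher and 7 passed (fry adjusted p = 0.211), with Spib, a B lineage and plasmacytoid dendritic cell transcription factor, at 1.42 ± 0.721 CPM against 0.325 ± 0.0960 CPM and Cd22, a B cell surface lectin, at 1.49 ± 0.822 CPM against 0.404 ± 0.0270 CPM. In the plasma cell list 9 of 11 were higher and 2 passed, the immunoglobulin constant genes Ighg1 and Igkc. Ighg1 was at 22.15, 14.3, 1 and 0.83 CPM in GrB-Fc-KS49 replicates 1 to 4. In the immune checkpoint list 14 of 17 were higher and 0 passed, with Pdcd1, which encodes PD-1, at 3.43 ± 2.70 CPM against 0.612 ± 0.369 CPM. In the lymph node and tertiary lymphoid list 6 of 8 were higher and 3 passed: Ltb, Ccr7 and Cxcl13, a B cell attracting chemokine at 4.40 ± 2.67 CPM against 0.427 ± 0.336 CPM.

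The lymphocyte lists were highest in GrB-Fc-KS49 replicates 1 and 2, while markers of other tissues were carried by replicates 1, 2 and 3. Replicate 3 had a T cell score of -0.60 and a skeletal muscle score of 0.44, against 0.39 for muscle in replicate 2. Pvalb, a fast muscle protein, was at 93.18, 6.27, 5.57 and 0.53 CPM in GrB-Fc-KS49 replicates 1 to 4 and at 0.12 to 1.75 CPM in controls. Krt10, a keratin of the epidermis, was at 1.97, 725.05, 0.38 and 0.25 CPM, and at 0.23 to 0.32 CPM in controls. All 17 skeletal muscle genes were higher in the treated mean with 0 passing when adjusted over the list alone, all 15 adipocyte genes were higher with 3 passing, and all 3 tested skin genes were higher and passed. The adipocyte score was highest in GrB-Fc-KS49 replicate 3, at 1.88, where Adrb3 and Lipe, a receptor and a lipase of fat cells, were at 1.53 and 22.37 CPM. Of the normal mammary epithelium genes 12 of 14 were higher and 1 passed, the whey acidic domain gene Wfdc18, and Krt5, a basal keratin, was at 202 CPM in GrB-Fc-KS49 replicate 2. In the carcinoma epithelial list 14 of 15 were higher and 0 passed, with Esrp1, an epithelial splicing regulator, at 11.37 CPM in the same library. Of the erythroid genes 7 of 8 were higher and 0 passed.

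Among myeloid lists, 17 of 18 dendritic cell genes were higher, and 7 higher and 1 lower passed when adjusted over the list alone (fry adjusted p = 0.247). Siglech and Ccr9, both expressed by plasmacytoid dendritic cells, were at 2.23 ± 1.01 CPM against 0.553 ± 0.193 CPM and at 1.69 ± 0.857 CPM against 0.358 ± 0.0573 CPM (SD, n = 4 each), and neither gene overlapped between the groups. Ccr9 lies opposite other genes on the same stretch of chromosome 9. In the macrophage list 18 of 23 were higher and 5 passed, with Apoe, a lipoprotein, at 736 ± 225 CPM against 297 ± 63.5 CPM, C1qa, a complement subunit, at 453 ± 226 CPM against 198.3 ± 34.4 CPM, and Trem2, a lipid receptor, at 42.3 ± 13.3 CPM against 24.7 ± 2.54 CPM. In the complement list 14 of 16 were higher and 4 passed, C2 among them. In the neutrophil list 14 of 17 were higher and 1 passed, G0s2, a lipase inhibitor, at 3.05 ± 0.426 CPM against 1.397 ± 0.450 CPM, while Wfdc21 had a log2 fold change of 2.49 ± 0.72 (SE). The monocyte list had 11 of 16 higher, the M1-type macrophage list 18 of 19, the M2-type list 10 of 19, and the mast cell list 12 of 13, with 0 passing in each. Hdc, which makes histamine, was at 8.995 ± 3.94 CPM against 4.95 ± 0.748 CPM. Of 2 eosinophil genes tested 1 was higher and passed.

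In the MHC class II list all 12 genes were higher and 10 passed when adjusted over the list alone (fry adjusted p = 0.297), and H2-Aa was at 953, 536, 42.5 and 115 CPM in GrB-Fc-KS49 replicates 1 to 4 and at 17.2 to 96.8 CPM in controls. In the MHC class I list 16 of 17 were higher and 0 passed, with the peptide transporter gene Tap2 at 189.1 ± 55.8 CPM against 125 ± 8.60 CPM (SD, n = 4 each). All 22 interferon gamma response genes and all 20 type I interferon response genes were higher in the treated mean and 0 passed in either list. Genes within each list moved together, with an estimated correlation of 0.96 in both. Interferon gamma scores were 1.75, 0.87, -1.12 and 0.04 in GrB-Fc-KS49 replicates 1 to 4 and -1.16 to 0.14 in controls. Type I scores were 1.5, 0.9, -1.47 and 0.35 against -1.09 to 0.11 in controls. Socs1, an inhibitor of cytokine signalling, was at 18.9 ± 10.4 CPM against 8.86 ± 0.773 CPM, and Isg15, a ubiquitin-like interferon-induced protein, at 69.0 ± 39.4 CPM against 33.4 ± 7.23 CPM. Their treated means were 13.9 and 51.1 CPM without GrB-Fc-KS49 replicate 1. Cxcl9, a chemokine for activated T cells, was at 240.94, 87.18, 2.12 and 29.26 CPM in GrB-Fc-KS49 replicates 1 to 4. In the chemokine list 22 of 26 were higher and 0 passed, with Ccl8 at 80.9 ± 66.4 CPM against 20.4 ± 2.28 CPM and Ccl5 at 10.6 ± 12.7 CPM against 1.83 ± 0.338 CPM, treated means of 48.3 and 4.46 CPM without GrB-Fc-KS49 replicate 1. Ccl5 was at 1.44 CPM in GrB-Fc-KS49 replicate 3 and at 1.54 to 2.22 CPM in controls. The NF-kB list had 13 of 21 higher, the pyroptosis list 13 of 15 and the granzyme and serpin list 11 of 16, with 0 passing in each. Pycard, an inflammasome adaptor, was at 9.50 ± 5.03 CPM against 4.64 ± 0.884 CPM.

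Among lists of cell processes and traits, 21 of 22 ribosomal protein genes and 16 of 20 oxidative phosphorylation genes were higher. When adjusted over the list alone 15 and 8 passed (fry adjusted p = 0.211 for both). Counts from whole tumours do not show which cells these lists, or those that follow, come from. Rps14 was at 401 ± 24.8 CPM against 304.5 ± 27.2 CPM, and the cytochrome oxidase genes Cox6a1 and Cox4i1 were at 118 ± 22.2 CPM against 82.96 ± 2.26 CPM and at 475 ± 85.6 CPM against 342 ± 24.2 CPM (SD, n = 4 each). Removal of the length and GC trends took the median log2 fold change from 0.29 to 0.14 for ribosomal protein genes and from 0.17 to 0.07 for oxidative phosphorylation genes. Over all genes it covers, the median went from 0.03 to -0.07. Part of the move of any list under this correction is therefore common to all genes. In the proliferation list 16 of 24 were lower, and 7 lower and 1 higher passed (fry adjusted p = 0.247), with Kif11, a spindle motor, at 78.4 ± 8.84 CPM against 102 ± 4.55 CPM. The proliferation score was -0.29, -0.99, -0.31 and 0.38 in GrB-Fc-KS49 replicates 1 to 4, against 0.2 to 0.45 in controls. Of EMP2 and its reported partners 12 of 17 were lower, and 8 lower and 1 higher passed (fry adjusted p = 0.247), with Hif1a, a hypoxia-inducible factor subunit, at 161 ± 42.3 CPM against 273 ± 13.2 CPM and Ptk2, the focal adhesion kinase, at 118 ± 13.6 CPM against 149 ± 6.49 CPM. The score of this list was -1.2, 0, -0.32 and 0.04 in GrB-Fc-KS49 replicates 1 to 4, against 0.04 to 0.6 in controls. At an unadjusted p under 0.05 were 9 lower and 1 higher of the 24 proliferation genes. For the 17 genes of EMP2 and its partners it was 8 lower and 1 higher, against 35.1% of all genes tested. In the epithelial-mesenchymal transition list 15 of 17 were lower and 0 passed (fry adjusted p = 0.297), with Zeb2, a repressor of epithelial genes, at 82.5 ± 7.43 CPM against 102 ± 2.99 CPM. Removal of the length and GC trends took the proliferation median from -0.14 to -0.17. It took the median of EMP2 and its partners from -0.32 to -0.39 and that of epithelial-mesenchymal transition from -0.26 to -0.37. The apoptosis and p53 target list had a mixed fry adjusted p of 0.0332 and was lower by the directional fry test with an adjusted p of 0.374, with 4 members lower and 1 higher passing. Casp8, the apical caspase of death receptors, was at 56.6 ± 4.10 CPM against 71.4 ± 1.55 CPM, Zmat3 at 59.98 ± 9.50 CPM against 81.8 ± 8.88 CPM, and Phlda3 at 71.2 ± 3.87 CPM against 59.6 ± 4.41 CPM. The median log2 fold change of this list was -0.13 (-0.24 after removal of the length and GC trends) and its mean 0.02. Of the cancer stem cell genes 8 of 16 were higher, and Prom1 (higher) and Bmi1 (lower) passed, with a median of -0.01 (-0.16 after removal of the trends), a mean of 0.31 and a lower direction by fry.

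Among vascular, stromal and stress lists, 16 of 20 endothelial genes were higher and 0 passed when adjusted over the list alone, with Egfl7 at 27.3 ± 7.76 CPM against 15.9 ± 3.06 CPM (SD, n = 4 each). All 3 tested lymphatic endothelium genes were lower with 0 passing. Of the pericyte and smooth muscle genes 7 of 13 were higher and of the fibroblast and matrix genes 9 of 20, with 0 passing in either, with a median of 0 and a mean of 0.16 for the pericyte list, while the fibroblast list had a median of -0.03 (-0.17 after removal of the length and GC trends), a mean of 0.14 and a higher direction by fry. Of the hypoxia genes 8 of 21 were higher, of the angiogenic factors 8 of 18, of the unfolded protein response genes 8 of 20 and of the immediate early and heat shock genes 9 of 20, with 0 passing in each. Sel1l, a component of endoplasmic reticulum degradation, was at 108 ± 8.89 CPM against 128 ± 5.49 CPM. Because the use of strand in counting is not given, the values of Rps14, Cox4i1, G0s2, Hif1a, C2, Egfl7 and Klrb1c, which share their place in the genome with another gene, are uncertain.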

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

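Of the tests in this part, the splits of the libraries for genes at an adjusted p under 0.05 or 0.10, at an unadjusted p under 0.05 and after trend removal, and for lists at an adjusted directional or mixed p by fry, as well as the test of noncoding genes on the strand of a protein-coding gene and the lymph node and tumour share tests with the values per tumour, were chosen after the results were seen. The correction for length and GC trends was also added after the data were seen, so any bound set for it postdates them.

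A tumour was singled out where its gap to the nearest of its group was more of the group's range than chance gives in about 1 in 20 groups. This occurred in 17 of 172 groups of named genes and 5 of 92 groups of list scores. The share of list scores is near the 1 in 20 that chance gives, and some of the gene flags may be chance as well. GrB-Fc-KS49 replicate 1 accounted for 8 of the flags. In that tumour, Nphs1 was at 198.9 CPM (the others 152.2 to 157.2), Rabac1 at 45.26 (37.09 to 38.46), Rplp1 at 917.8 (589.2 to 640.4), Cox6a1 at 151.3 (102.6 to 110.8), Cox4i1 at 603.3 (429.1 to 437), Gm37335 at 4.257 (0.3462 to 0.8684), and the muscle genes Pvalb and Tnnc2 at 93.18 (0.5347 to 6.272) and 166.9 (1.703 to 16.65). In GrB-Fc-KS49 replicate 2 the epithelial genes stood apart, with Esrp1 at 11.37 CPM (0.1878 to 0.8327), Krt5 at 202.2 (0.7387 to 3.985) and Krt10 at 725.1 (0.2487 to 1.966). In GrB-Fc-KS49 replicate 3 the pericyte score was 1.04 (-0.44 to -0.27) and the NF-kB score -1.16 (0.32 to 0.6). In GrB-Fc-KS49 replicate 4 Prom1 was at 0.3482 CPM (0.69 to 0.7137) and the erythroid score was -1.57 (0.63 to 0.95). Among controls, replicate 1 stood apart in Lipe at 5.997 CPM (8.432 to 8.727), Pdcd1lg2 at 0.2418 (0.1186 to 0.138), the T cell score at -1.11 (-0.39 to -0.32) and the pyroptosis score at -0.65 (-0.24 to -0.16). Bmi1 was at 126.5 CPM in control replicate 3 (106.2 to 108.7), and control replicate 4 stood apart in Casp8 at 69.03 CPM (72.01 to 72.27) and Krt5 at 2.033 (0.4957 to 0.7514).

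The number of genes at an unadjusted p under 0.05, 6915, was the largest of 35 splits of the 8 tumours into 4 and 4, reached by 1 split, with 3369 in the highest other split. This argues against chance for this count but cannot exclude it, since 1 of 35 is the smallest share these splits can give and several counts were tried. The same holds for DESeq2 (1 split, 4726 against 656), for an adjusted p under 0.10 (1 split, 4952 against 0) and after removal of the length and GC trends (1 split, 6183 against 4145). The splits do not argue against chance for the lists at an unadjusted p by fry (3 splits, 6 against 11), for the 1 list at an adjusted mixed p by fry (3 splits, 1 against 2) or for camera (13 splits, 28 against 33). A count of 0 is reached by any split, so the 35 splits say nothing about chance for the genes at an adjusted p under 0.05 or the lists at an adjusted directional p (35 splits each, 0 against 0). After removal of the trends 6183 genes were at an unadjusted p under 0.05 against 6800 before, 5163 of them in both and 1020 new, and 6183 lies above the other 34 splits but below the bound of 1.5 times the highest of them that had been set beforehand, so how far the trends account for the count stays open.

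Genes of the types TEC (transcripts still awaiting experimental proof) and lncRNA had higher treated means more often than not, 500 of 679 and 1411 of 2043, while the median log2 fold change of protein-coding genes was 0.01. Reads shared with overlapping protein-coding genes are argued against as the whole cause, since the 1037 of them that overlap none had a median of 0.22 (95% bootstrap interval over genes, not tumours, 0.19 to 0.24) against 0.29 for the 1685 that overlap one. For the 508 on the same strand as a protein-coding gene that explanation stays open, with a median of 0.75 (0.63 to 0.87), over 2 times that of genes that overlap none, while those on the opposite strand had 0.20 (TEC) and 0.21 (lncRNA). The length and GC trends are argued against as well, with 0.18 (0.16 to 0.21) after removal against 0.26 before on the same 2389 genes. Unspliced or genomic reads were not tested and stay open, and no biological explanation was tested.

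The 56 lymphocyte marker genes had a median log2 fold change of 1.88 (1.26 without GrB-Fc-KS49 replicate 1). Lymph node tissue taken along is argued against by the low level of 8 lymph node stroma and B cell genes, of which the highest treated mean was 1.277 CPM (Ccl21a) against 4.6 CPM for Cd3e. Without GrB-Fc-KS49 replicate 1 the treated mean of Cd3e was 2.48 CPM, so this argument rests in part on 1 tumour. The length and GC trends are argued against by a median of 1.79 (95% bootstrap interval over genes 1.44 to 1.98) after their removal. The endothelial list was at 0.23 (interval of the difference over genes 1.25 to 1.92), but genes of a list move together, and between tumours the difference of the medians was 2.41, 2.14, -0.8 and 1.03 in GrB-Fc-KS49 replicates 1 to 4 and -1 to 0.68 in controls (exact permutation p = 0.2), so a lower share of tumour cells stays open. Recruitment of lymphocytes and their presence in adjoining tissue stay open too, as Ccl21a was at 0.0182 CPM in controls and the muscle and adipocyte lists were also higher, at 2.88 (1.20 without GrB-Fc-KS49 replicate 1) and 1.69 (0.50 without replicate 3).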

How the results depend on the processing

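The correction for length and GC trends was chosen after the results were seen, and the other alternatives before the data were examined. Of 1952 values for 86 named genes, 1737 kept direction and side of the threshold, 207 passed it and 8 reversed, all of Emp2. Of 857 values for 43 lists, 799 kept both, 28 passed the threshold and 30 reversed, in 8 lists. DESeq2 called 4726 genes (2219 higher, 2507 lower), limma-voom 1 (1 lower), sample weights 1291 (471, 820) and an adjusted p under 0.10 gave 4952 (2272, 2680). Leave-one-out calls ran from 0 to 3447 (higher 0 to 1432, lower 0 to 2015), with 1260 (445, 815) without GrB-Fc-KS49 replicate 1 and 3447 without replicate 4. Lower genes at an unadjusted p under 0.05 ran from 2301 to 3803 in leave-one-out fits, and higher ones fell to 2013 after the length and GC correction. That correction also took the median log2 fold change of all genes it covers from 0.03 to -0.07. Camera with a preset correlation called 28 lists (25 higher, 3 lower) and 29 at an unadjusted p, and with an estimated correlation 0. Leave-one-out lists at an unadjusted p by fry ran from 3 to 20. The log2 fold change of Emp2 was -0.01 with no filter, by DESeq2 and by limma-voom, 0 with the U suffix as covariate, and -0.1 to 0.11 in leave-one-out fits. The direction of a list is that of its test, fry or the score, so it can turn where the median keeps its sign. Medians of the lists whose test direction turned were as follows. Both U libraries left out gave fibroblast -0.14, pericyte -0.01, hypoxia 0.06, angiogenic 0.05 and immediate early 0.04. The suffix as covariate gave fibroblast -0.07 and pericyte -0.01. The length and GC correction gave fibroblast -0.17 and pericyte 0, the permutation fibroblast -0.03, and no filter pericyte -0.01. The stricter filter gave hypoxia 0 and angiogenic 0.02, log2 CPM plus 1 angiogenic 0, and members of 1 list only granzyme 0.15 and cancer stem cell 0.01. Leave-one-out medians were monocyte 0.05 to 0.51, pericyte -0.25 to 0.28, fibroblast -0.29 to 0.15, granzyme 0.04 to 0.81, hypoxia -0.16 to 0.04, angiogenic -0.08 to 0.06, cancer stem cell -0.08 to 0.02 and immediate early -0.11 to 0.02. The cause was not tested. Upper quartile factors, DESeq2 and limma-voom were not run for lists. No paired analysis was made because the labels give no pairs. Depth limits which genes can be tested: 19718 of 26709 passed the low-count filter. In counts simulated at the real depth with 4 tumours per group 25.4% of 1.5-fold changes were recovered. Those counts had independent genes and the same dispersion in both groups, so this share need not hold here, where the treated tumours spread more.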

Other observations

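The search for genes absent from 1 group, the comparison of constant-region genes and the comparison of the tumours with the U suffix were all chosen after the results were seen.

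Constant-region genes of antigen receptors differed between single treated tumours. Iglc3, an immunoglobulin light chain, was at 0.66, 0.72, 0.18 and 0.22 CPM in GrB-Fc-KS49 replicates 1 to 4 and at 0.07 to 0.11 CPM in controls. Igha, the chain of IgA, was at 4.68, 2.05, 0.29 and 0.47 CPM against 0.15 to 0.82 CPM. Trdc, the constant region of the delta chain of gamma delta T cells, was at 1.063 ± 0.238 CPM against 0.7285 ± 0.194 CPM (SD, n = 4 each). Trbc2, of the beta chain, was at 8.16, 3.3, 0.33 and 1.57 CPM in GrB-Fc-KS49 replicates 1 to 4 and at 0.21 to 0.58 CPM in controls, with a treated mean of 3.34 CPM that was 1.73 CPM without replicate 1.

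In 4 genes every tumour of 1 group had 0 counts and every tumour of the other had at least 10, while 0 such genes were found in any of the 34 other splits. All 4 are lncRNAs opposite a protein-coding gene, and were named after their values were seen. Gm15655 (chromosome 8, 116431817 to 116433972), opposite the transcription factor gene Maf, was at 0.2706 ± 0.0827 CPM in controls and 0 in treated tumours, at least 7.19-fold lower against a floor of 3 counts per library. Gm20659 opposite Dusp3, Gm37335 opposite Hs6st1 and Gm45732 opposite Urb2 were at 0 in controls and at 2.237 ± 2.28, 1.502 ± 1.85 and 1.573 ± 1.88 CPM in treated tumours, at least 57.9-fold, 38.9-fold and 40.7-fold higher. Each was highest in GrB-Fc-KS49 replicate 1, without which the bounds are 31.0-fold, 15.1-fold and 16.9-fold. Among their partners, none of which passed, Dusp3 was at 44.07 ± 5.30 CPM against 56.84 ± 7.30 CPM in controls, Hs6st1 at 37.97 ± 8.60 CPM against 45.97 ± 3.63 CPM and Urb2 at 64.08 ± 15.2 CPM against 96.46 ± 8.32 CPM, while Maf was at 75.12 ± 21.5 CPM against 59.36 ± 7.24 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0738, 0.214, 0.0625 and 0.265). How reads were divided between such pairs is not given in the sources used here, so these values are uncertain.

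Gm29216 (chromosome 1, 24654787 to 24655278), a pseudogene copy of mitochondrial sequence, was at 575 ± 438 CPM in treated tumours against 6.241 ± 3.88 CPM in controls (364 CPM without GrB-Fc-KS49 replicate 1), and mt-Co1, which it resembles, at 5910 ± 440 CPM against 6625 ± 450 CPM (SD, n = 4 each). Both genes were named after their values were seen. Reads of near-identical copies cannot be told apart in a table of counts.

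The tumours with the U suffix, IgG control replicate 1 and GrB-Fc-KS49 replicate 3, stood at the same end of their group in 19 of 46 list scores, more than in any of the other pairs of 1 control and 1 treated tumour, where the highest was 13. Of the 16 pairs 1 must be highest whatever the suffix means. The lists share genes and move together, so the 19 scores are not independent, and an effect of the suffix was not tested. For the tumours with the suffix, single scores were as follows. Their scores were -1.09 and -1.47 for type I interferon response, -1.22 and -0.82 for MHC class I, and 0.91 and 1.15 for fibroblast and matrix genes.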
